A study of Mus musculus with 4 samples.

How the data were processed

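ChIP-seq with antibodies against H3K4me3 and H3K9me3 was carried out on thioglycollate-elicited peritoneal macrophages of wild-type and Sun-/- C57BL/6 mice, per the labels. There was 1 library per mark and genotype, and the group of each was taken from its labels. CASAVA 1.4, Bowtie 0.12.8, MACS 1.4.2 and DiffBind were named, with the build mm10, per the submitters' processing notes. Their order and roles were not given in the sources used here.

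Each deposited file was a peak list made by the authors for a single library. Peaks were called with MACS 1.4.2 without a control library, with a p-value limit of 1e-05, an effective genome size of 1.87e+09, a band width of 300, a model fold range of 10 to 30 and at most 1 tag per position, per the file headers. The background of each peak was taken from up to 10000 bp around it, per the file headers, so broad domains raise their own background. Totals were 37378032, 31391199, 33007219 and 32859785 tags for H3K4me3 wild type, H3K4me3 knockout, H3K9me3 wild type and H3K9me3 knockout, of which 29681491, 26748289, 27727997 and 28586946 remained after duplicate removal, per the file headers. Tags were 50 bp long, and 49 bp in the H3K4me3 knockout library, per the file headers. The fragment size estimate was 142 and 149 bp for H3K4me3, but 66 and 71 bp for H3K9me3, per the file headers. The H3K9me3 estimates are close to the tag length, and the position, width and calling of H3K9me3 peaks can depend on them, which was not tested here.

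The deposited values per peak were the tag count, the score (-10 times log10 of the p-value), the fold enrichment over the caller's background, a linear ratio, and the width and summit, other measures in bp. Score and fold enrichment are the authors' own values for each peak and were used only to describe, rank or filter peaks within a list.

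Overlaps were computed with bedtools 2.31.1, and all else with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. A peak was shared if at least 1 bp overlapped a peak of the other genotype. The background was the mean over 200 random placements on the same chromosomes, from position 3000000 on. Shares have exact Clopper-Pearson 95% intervals. Peaks were paired if they overlapped each other, and no other peak, by at least 50% reciprocally and held at least 50 tags in 1 of both libraries. The log2 ratio of tags per kb, knockout over wild type, was centred on the median pair, or scaled to filtered tags where stated, with an exact conditional binomial interval. The size rule was at least 2-fold. With 1 library per group no test between genotypes was run.

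Genes came from a RefSeq table of GRCm38.p6, the same assembly as mm10, with 49943 genes, 21887 of them protein-coding. The table used gave no strand and no exons. The plan set before the data were examined called for peaks near transcription starts. Peaks within 1000 bp of either gene end were used instead, and positions were not assigned to exons or introns.

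The named genes followed a rule fixed before the data were examined. It took, per mark, the 10 protein-coding genes with the most tags in a peak of each genotype without a partner, the 10 pairs with the highest and the 10 with the lowest centred ratio among those of at least 100 tags in total, from each of 23 fixed gene lists up to 4 members marked in either genotype alone, and the SUN domain genes. Other members of the fixed lists are named as examples of their list, by their values, and genes outside the rule are said to be chosen after their values were seen. Not every gene the rule takes is reported here. List medians are given as percentiles among 10000 random lists of the same size matched on tags. Lists with fewer than 5 paired members have no percentile.

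The computation was tested on simulated data made from the wild-type lists, with 70.0% of the peaks kept and 100 peaks each made 4-fold higher or lower. It found 70.0% shared for both marks. The kept peaks had unchanged positions and widths, so this share was fixed in advance. The effect of widths called separately in each library was not simulated. For H3K4me3 the computation recovered 100 higher and 100 lower peaks with 4 false calls among 14653 pairs. For H3K9me3 it recovered 100 and 99 with 1 false call among 654 pairs. A true log2 scale of -0.32 was found as -0.33 for H3K4me3 and as -0.38 for H3K9me3. The tolerance of this check was widened after the H3K9me3 result was seen. The H3K9me3 shift is larger than the H3K9me3 median of -0.02 in the report, which cannot be told from 0 by this measure.

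Alternatives were an overlap of 50% of the peak, a score of at least 100 in both lists or in the list asked, equal numbers of peaks, merging within 1000 bp, scaling to library totals or to filtered tags, tags without division by width, 80% reciprocal overlap, minimums of 20 and 100 tags, windows of 500 and 2500 bp, and H3K9me3 peaks away from H3K4me3 peaks. The last and the scaling to filtered tags as an alternative to centring were chosen after seeing the data.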

Results

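Chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map 2 histone modifications in thioglycollate-elicited peritoneal macrophages of 8-week-old C57BL/6 mice. H3K4me3 marks the promoters of active genes, and H3K9me3 marks silenced chromatin. Each mark was mapped in wild-type cells and in cells from mice that the labels call Sun-/-, here called Sun knockout, with 1 library per mark and genotype and 4 libraries in all. The labels do not say which gene Sun stands for. After removal of duplicate tags the libraries held 29681491 tags (H3K4me3, wild type), 26748289 (H3K4me3, Sun knockout), 27727997 (H3K9me3, wild type) and 28586946 (H3K9me3, Sun knockout). No difference between genotypes has a replicate check, so no p-value was computed, and all intervals are 95% intervals that cover counting error only. Coordinates are those of the mouse build mm10.

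The gene removed in the knockout could not be checked, because the labels do not name it and the peaks at gene ends can lie outside a deleted part. Sun1 and Sun2, which encode inner nuclear membrane proteins that link the nucleus to the cytoskeleton, had an H3K4me3 peak at a gene end in both genotypes. The strongest Sun1 peak (chromosome 5, 139200587 to 139202412 in the wild type) held 359 tags in the wild type and 259 in the knockout, with a centred log2 tag density ratio of 0.06 (interval -0.18 to 0.29). The Sun2 peak on chromosome 15 held 473 and 299 tags, with a ratio of -0.20 (-0.41 to 0.01). Sun3 held 101 and 76 tags and Spag4 343 and 254 tags in their H3K4me3 peaks. Sun5 carried an H3K9me3 peak of 65 tags in the wild type and 67 tags in the knockout, on chromosome 2. At Sun1 an H3K9me3 peak of 12 tags was called in the knockout alone.

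The first comparison asked how the H3K4me3 map differed without Sun. Of 21887 protein-coding genes, 13205 had a peak within 1000 bp of a gene end in both genotypes, 649 in the wild type alone and 259 in the knockout alone. The wild-type list held 31398 peaks over 41.2 Mb and the knockout list 28505 peaks over 35.5 Mb. The knockout library was smaller, with 26748289 filtered tags against 29681491, and these counts were not adjusted for depth. Of the wild-type peaks, 71.9% (interval 71.4 to 72.4%) overlapped a knockout peak, and 80.2% (79.8 to 80.7%) of the knockout peaks overlapped a wild-type peak, against 2.98% and 3.30% at random positions. The peaks without a partner were weak, with a median of 33 tags in the wild type and 27 in the knockout, against 156 and 109 for shared peaks. Peaks with a score of 400 or more were shared in 10207 of 10210 cases for the wild type and in 7179 of 7182 for the knockout.

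**Figure D1:**
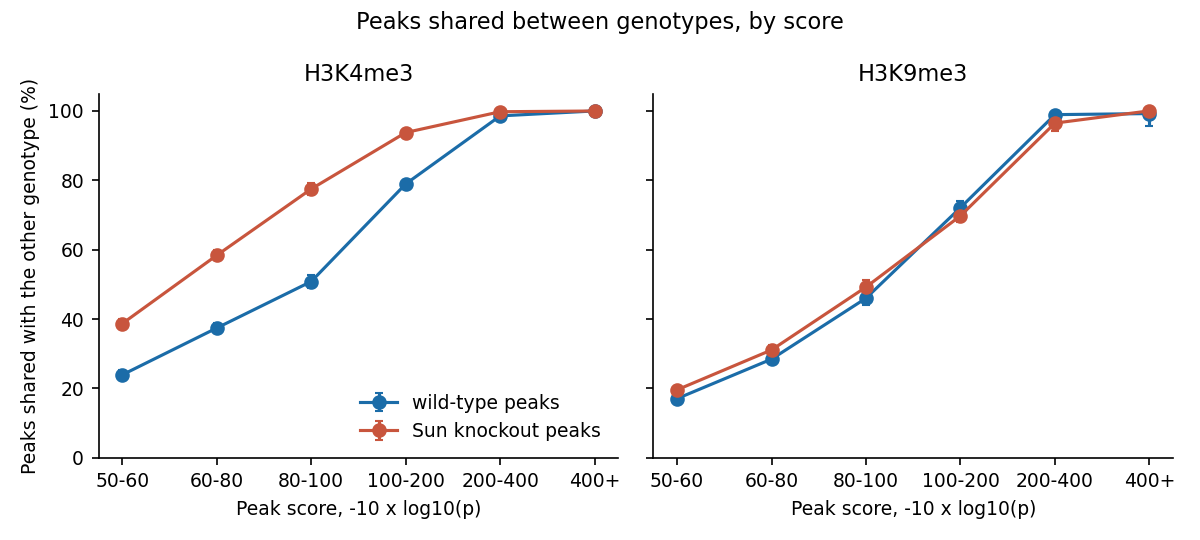
Share of peaks (%) that overlap a peak of the other genotype, by the authors' peak score, for H3K4me3 (left) and H3K9me3 (right); points are shares in 1 library each and bars are 95% binomial intervals. For wild-type H3K4me3 the share goes from 23.9% in the lowest score class to 99.97% in the highest, and for wild-type H3K9me3 from 17.1% to 99.2%.

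The 6 H3K4me3 peaks of such high score that had no partner were looked up after their values were seen. In the wild type they lay at Tnf, which encodes the cytokine tumour necrosis factor, at Prkcd, a protein kinase C gene, and within Rhbdf2, whose product takes part in the release of that cytokine. In the knockout they lay at Gnai2, a G protein subunit gene, Slc43a2, an amino acid transporter gene, and Trim8. The Tnf peak (chromosome 17, 35199666 to 35202081) held 348 tags with a score of 486, while a neighbouring peak from 35193949 held 257 tags in the wild type and 241 in its knockout counterpart. The Gnai2 peak (chromosome 9, 107631574 to 107635409) held 636 tags with a score of 528.

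Among the tag-rich genes with a peak in the wild type alone were Zc3h12a, which encodes an RNase that degrades cytokine mRNAs, with 1201 tags, Lrp1, a scavenger receptor gene, with 1201 tags, and Rhog, a small GTPase gene, with 1129 tags. Ankrd13b and Git1 shared a peak of 1439 tags, and a peak of 1167 tags overlapped Cd151 and Cracr2b and ended within 1000 bp of Polr2l. Rab11fip5 had 1130 tags and Jmjd8 had 1079. In the knockout alone, Ppp1r9b had 1359 tags, Tnfaip2, a gene induced by tumour necrosis factor, had 1205 tags, Fam20c had 985, Trim8 had 806, and Mef2d, a transcription factor gene, had 713. Brd2 and H2-DMa shared a peak of 625 tags, Timp2, a metalloproteinase inhibitor gene, had 624, and Pip5k1c had 611. Cracr2b, Polr2l, Rab11fip5, Tnfaip2, H2-DMa and Pip5k1c had another peak at a gene end in the other genotype. Peaks of at least 300 tags without a partner were few, 51 of 5904 in the wild type and 25 of 3182 in the knockout. Their median score was 98.3 in the wild type and 111 in the knockout, against 836 and 646 for shared peaks of that size.

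In peaks that paired between genotypes, H3K4me3 tag density was lower in the knockout library, by an amount that depended on the scaling. Scaled to the filtered tags of each library, the median log2 ratio of 17114 pairs was -0.19 (0.877-fold), and 78.5% of the pairs lay below 0. Scaled to the library totals before duplicate removal, the median was -0.09 (0.941-fold), with 64.9% below 0. The peaks held 17.8% of the tags in the wild-type library and 14.0% in the knockout library. All ratios of single genes below are relative to the median pair. The pairs then had an SD of 0.24, against 0.19 for counting error of the tags alone, and with tags per peak the SD was 0.34. By density, 7 pairs were at least 2-fold denser and 2 at least 2-fold less dense in the knockout. With tags per peak in place of density these counts were 252 and 24, with scaling to filtered tags 1 and 11, with scaling to library totals 4 and 2, and with at least 100 tags in a pair 4 and 0.

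**Figure D2:**
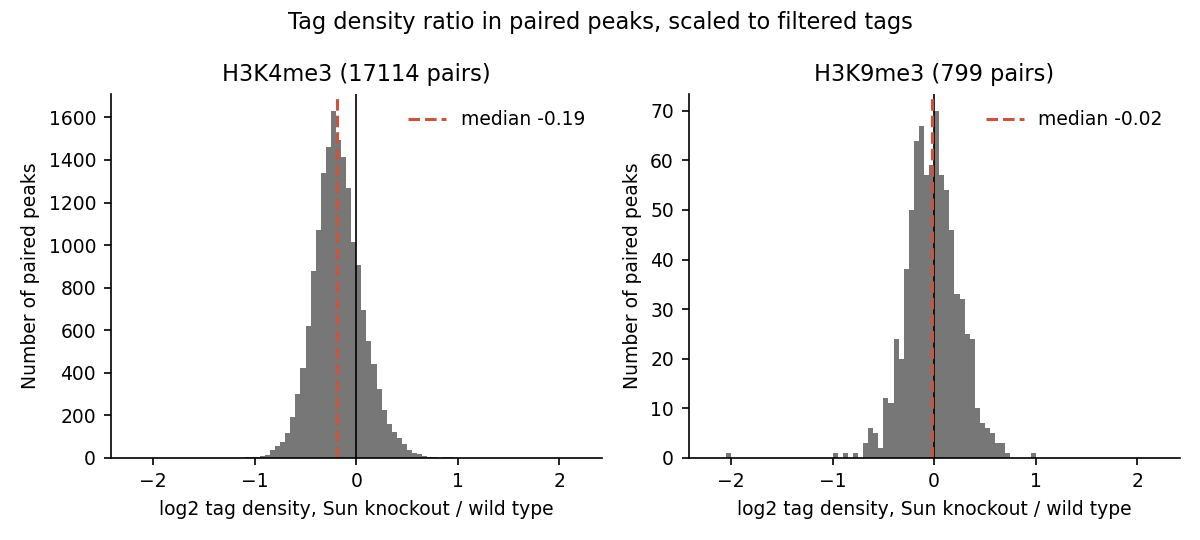
Number of paired peaks by log2 ratio of tag density, Sun knockout over wild type, scaled to the filtered tags of each library, for 17114 H3K4me3 pairs (left) and 799 H3K9me3 pairs (right), 1 library per genotype. The dashed line is the median, -0.19 for H3K4me3 and -0.02 for H3K9me3.

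Helz2, an interferon-inducible helicase gene, had the highest ratio of the named pairs, 1.01 (interval 0.81 to 1.22), with 312 tags in the wild type and 525 in the knockout. It was followed by Tex12, a meiosis gene, at 0.98, C1rl at 0.97, Nrxn2 at 0.89, Disp3 at 0.87, Wdr88 at 0.83, the histone gene H4c8 at 0.80, Slc2a6, a hexose transporter gene of macrophages, at 0.80, and Cdx1 at 0.77. A peak shared by Ceacam16 and Gm19345 was at 0.83. The lowest ratio was that of a peak inside Tmem209, at its end next to Ssmem1, -1.19 (-1.76 to -0.64), with 97 and 39 tags. Pycrl was at -1.02, Cox6b1, a subunit gene of cytochrome c oxidase, at -0.86, Gna13, a G protein gene, at -0.86, Rab3a at -0.85, Ms4a6b at -0.84, Bnip2 at -0.83, Nme1 at -0.82, Epha3 at -0.80, and Gtf3c1 at -0.80. Several of these peaks differed in width between the genotypes, such as that of Gna13 with 1236 bp in the wild type and 2162 bp in the knockout. Gna13, Rab3a, Bnip2 and Gtf3c1 held 364, 276, 294 and 269 tags in the wild type and 277, 222, 220 and 241 in the knockout. Their knockout peaks were wider, so their low ratios depended on the division by width. Among the highest ratios, Nrxn2, Wdr88 and H4c8 held fewer tags in the knockout (221 and 193, 57 and 50, 109 and 77), in narrower peaks.

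The fixed gene lists were then compared. Of 36 inflammatory cytokine and NF-kB target genes, 20 had H3K4me3 at a gene end in both genotypes, 2 in the wild type alone (Tnf and Il10) and 6 in the knockout alone. The latter included Csf3, the granulocyte colony-stimulating factor gene, with 202 tags, the chemokine gene Ccl5 with 80, the acute phase gene Saa3 with 80 and the cytokine gene Il23a with 53. A wild-type peak that ended at 46710909, just outside the Saa3 window, had a knockout counterpart of 60 tags. For Il10 a knockout peak from 131020925 to 131021985 lay inside the gene, outside the window. The 15 paired members had a median centred log2 ratio of 0.11, above 96.9% of 10000 random lists matched on tags. Il6 was at 0.68 (0.09 to 1.28) with 37 and 79 tags, and Nfkbia, which encodes an inhibitor of NF-kB, was at -0.38 (-0.58 to -0.19) with 700 and 300 tags.

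Pattern recognition receptor genes and their signalling genes lay on the other side. Their 31 paired members had a median of -0.13, above 0.675% of random lists, and 27 of them were below 0. In all, 40 members had H3K4me3 in both genotypes, and those without a pair are outside this median. They went both ways in unscaled tags, such as Nod2 (208 and 492) and Myd88 (706 and 292). Irak3, a negative regulator of Toll-like receptor signalling, was at -0.53 (-0.79 to -0.27), Ticam2, a Toll-like receptor adaptor gene, at -0.45, Tlr4, the lipopolysaccharide receptor gene, at -0.27 (-0.62 to 0.09) and Tlr2 at -0.20 (-0.47 to 0.07). Chuk, a kinase gene of the NF-kB pathway, was at 0.55 (0.27 to 0.82). Tlr13 had a peak of 48 tags in the wild type alone. Type I interferon and antiviral genes had a median of -0.06 over 21 paired members, above 31.1% of random lists, and members went both ways. Irf7, a transcription factor gene of the interferon response, was at 0.73 (0.52 to 0.94), Isg20 at 0.69 and Bst2 at 0.57, while Irf9 was at -0.45 and Ifnar1, an interferon receptor gene, at -0.36. The median leaves out members marked in both genotypes without a pair. Of these, Zbp1 (148 and 347 tags), Mx1 (155 and 265), Mx2 (303 and 407) and Oasl1 (126 and 239) held more unscaled tags in the knockout. So did Rsad2 (135 and 217), Oas2 (128 and 181), Gbp3 (163 and 180) and Ifnb1 (21 and 59). Cmpk2 (378 and 353), Gbp2 (97 and 56) and Ifit3 (60 and 36) held fewer. The peaks counted for a member without a pair can differ in place and extent between genotypes. Such counts therefore do not measure a change. Usp18 and Ifit2 had a gene-end peak in the wild type alone, although a knockout peak of 169 tags began at 121246921, just beyond the wild-type Usp18 peak, which ended at 121246281.

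Macrophage identity genes had H3K4me3 in both genotypes for 28 of 40 members. The 22 paired members had a median of 0.03, above 85.7% of random lists, with Axl, a receptor for apoptotic cells, at 0.42 and Cebpa at -0.23. Members marked in both genotypes without a pair are outside this median and went both ways in unscaled tags. Spi1 held 38 and 503 tags, Aif1 127 and 281, and Trem2 230 and 313. Ctsb held 804 and 369, Cebpb 751 and 527, and Itgax 191 and 74. Peaks without a pair can differ in place and extent between the genotypes, so these counts do not measure a change. Ctss, Tfec and Icam2 had a peak in the wild type alone, although a knockout peak of 120 tags lay just outside the Ctss window, beside a wild-type peak of 140 tags. Alternative activation genes had a median of -0.01 over 13 paired members, above 56.1% of random lists, with Stat6 at 0.29 and Socs1 at -0.35. Ccl17 was marked in the wild type alone. H3K4 methylation machinery genes had a median of -0.02 (59.5%), H3K9 methylation machinery genes -0.11 (7.45%), SUN domain and nuclear envelope genes -0.05 (33.8%), and housekeeping genes -0.05 (28.8%). Tmpo, a nuclear envelope gene, had a peak of 97 tags in the wild type alone.

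Markers of other cell types were marked in part in both libraries: 5 of 18 mesothelial and fibroblast markers, 6 of 20 T and NK cell markers, 6 of 14 B cell markers, 5 of 10 dendritic cell markers, 2 of 15 neutrophil markers and 2 of 16 eosinophil and mast cell markers had H3K4me3 in both genotypes. Of the mesothelial and fibroblast markers, Upk3b, Krt8, Col1a2 and Krt19 had H3K4me3 in the wild type alone and 0 in the knockout alone, while the 3 paired members, Wt1, Krt18 and Col1a1, were at 0.23, 0.25 and 0.01. Cd5 and Il7r of the T and NK cell markers, Tpsab1 of the eosinophil and mast cell markers and Mmp8 of the neutrophil markers were marked in the wild type alone, and the neutrophil markers Camp and S100a8 in the knockout alone. The 14 B cell markers and 10 dendritic cell markers had 0 members in either genotype alone. The paired dendritic cell markers had a median of 0.17 over 5 members, above 96.1% of random lists, and the T and NK cell markers -0.06 over 5 members, above 40.2%.

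The 307 paired zinc finger genes had a median H3K4me3 ratio of -0.10, lower than every one of 10000 random lists. Zfp821 with 155 tags was the most tag-rich of 8 members marked in the wild type alone, and Zfp811 with 89 tags of 6 members marked in the knockout alone. Imprinted genes had a median of 0.11 over 19 paired members, above 97.9% of random lists, with Blcap at 0.52, Gnas at 0.50 and Kcnq1ot1 at -0.39. Nnat and Ndn were marked in the wild type alone. Neuronal genes had a median of 0.07 (79.6%), and Nefl, Syp and Neurod1 were marked in the wild type alone. Histone genes, 59 of 59 marked in both genotypes, had a median of -0.05 (41.6%), and clustered protocadherin genes -0.06 (39.3%). Under scaling to filtered tags the medians of the inflammatory, macrophage identity, imprinted, neuronal and dendritic cell lists turned negative, at -0.08, -0.16, -0.08, -0.12 and -0.02, while under scaling to library totals the inflammatory, imprinted and dendritic cell lists stayed above 0, at 0.02, 0.02 and 0.08. With a window of 2500 bp, Il10, Saa3, Usp18, Ctss, Tfec, Cd5, Neurod1, Nnat and Zfp821 had a peak in both genotypes. With 16 lists given a percentile for this mark, some would lie near an end without any difference between genotypes.

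**Figure D3:**
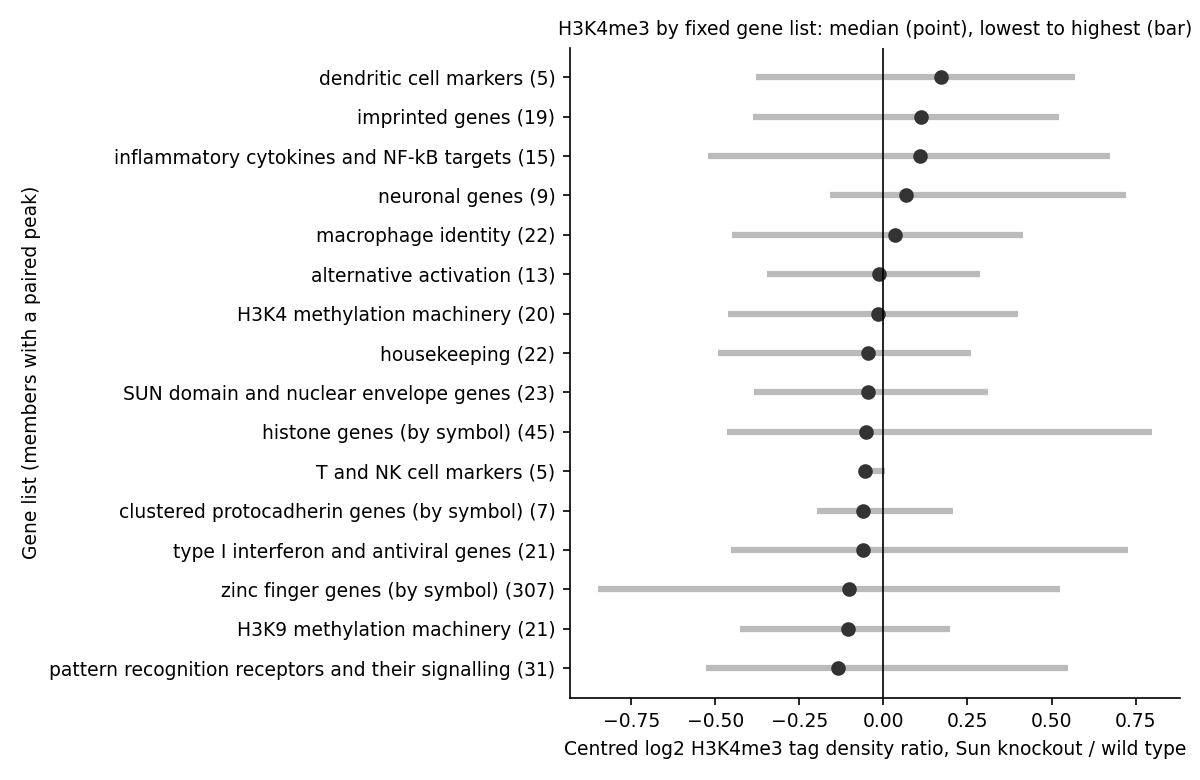
Centred log2 H3K4me3 tag density ratio, Sun knockout over wild type, in gene lists with at least 5 paired members (number in brackets), 1 library per genotype. Points are list medians and bars run from the lowest to the highest member; the medians range from -0.13 for pattern recognition receptors to 0.17 for dendritic cell markers, and every positive median turns negative when scaled to filtered tags.

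The second comparison asked how H3K9me3 differed without Sun. Peaks were short and weak in both genotypes, and most were called in only 1 of them. The wild-type list held 19279 peaks over 5.68 Mb with a median of 16 tags, and the knockout list 17369 peaks over 5.56 Mb with a median of 17 tags. The peaks held 1.69% and 1.62% of the tags. The caller's fragment size estimate for this mark was 66 and 71 bp, close to the tag length of 50 bp, and how far the peaks depend on it was not tested. Of the wild-type peaks 32.5% (31.8 to 33.1%) overlapped a knockout peak, and 35.8% (35.1 to 36.5%) the other way round, against 0.423% and 0.465% at random positions. With a score of at least 100 in both lists these shares were 48.3% and 46.0%, so their order depended on the limit. Among protein-coding genes, 3525 had a peak in the gene body in both genotypes, 1831 in the wild type alone and 2299 in the knockout alone.

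Over 799 pairs the median log2 ratio scaled to filtered tags was -0.02. It was 0.01 with tags per peak and 0.03 with scaling to library totals, so its sign depended on the measure. Their SD of 0.26 in tag density was close to the 0.25 of counting error of the tags alone, but with tags per peak it was 0.48. Width was called in each library, so the closeness in density does not show that pairs differed only by counting error. After centring 0 pairs were at least 2-fold denser and 1 at least 2-fold less dense in the knockout, with tags per peak these counts were 30 and 8, and with scaling to library totals 1 and 1.

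That pair lay in Ctnnb1, which encodes beta-catenin, on chromosome 9 at 120950470 to 120950819, with 90 tags in the wild type and 20 in the knockout and a ratio of -2.01 (-2.79 to -1.30). The wild-type library had 9 H3K9me3 peaks in this gene, all between 120950470 and 120959577, with 25 to 136 tags each and 685 in total. The knockout library had 2 peaks in the gene, with 35 tags in total. Over the same stretch the H3K4me3 knockout library had 2 peaks, of 117 and 89 tags, and the H3K4me3 wild-type library had 0.

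Other tag-rich H3K9me3 peaks without a partner lay largely in genes that had peaks in both genotypes. In the wild type these were Sfi1 with 771 tags, A530032D15Rik with 544, Gm7592 with 189, Gm38510 with 161, Hjurp, a chaperone gene of centromeric chromatin, with 120, and Zfp978 with 104. Gm40369, Gm36327 and Gm40365, neighbours on chromosome 6, had 255, 244 and 218 tags in the wild type and no knockout peak. In the knockout they were Plec, which encodes a cytoskeletal linker, with 696 tags, Sfi1 with 319, Sp110 and Sp140, immune nuclear body genes that shared a peak of 258, and Fam171a2 with 125. Mroh2a with 242 tags, the transcription factor gene Insm1 with 109 and Hunk with 94 had no wild-type peak. Among pairs at protein-coding genes taken by the naming rule, the highest ratios were those of Copg2 at 0.68 (0.19 to 1.18), Cacna1b at 0.60, Trim30d at 0.59 and a peak shared by Il18 and Tex12 at 0.58 (0.07 to 1.12). Ddx4, a germline helicase gene, was at 0.52 (-0.04 to 1.10). After Ctnnb1 the lowest among them were a peak shared by Zfp981 and Zfp993 at -0.63 (-1.23 to -0.04), Dop1b at -0.60, Grk5 at -0.57 (-1.15 to 0.02), a second Zfp993 peak at -0.55, Zfp984 at -0.54 (-1.13 to 0.03) and Gm7592 at -0.52. The zinc finger peaks among these held fewer tags in the knockout. Dop1b (55 and 58 tags), Grk5 (50 and 53) and Gm7592 (93 and 117) held more. Their knockout peaks were wider, so their low ratios came from the division by width. Dop1b also had a knockout peak of 93 tags without a partner.

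Gene families differed in how often they held H3K9me3 peaks. Zinc finger genes held 375 peaks in the wild type and 327 in the knockout, 3.35 and 3.25 times the number at random positions. As a fixed list, their 20 paired members had a median centred ratio of -0.07, above 6.37% of random lists. A set by pair, not part of the fixed lists, took 135 pairs of at least 20 tags at zinc finger genes. Its median centred ratio was -0.13, lower than every one of 10000 random sets, but without chromosome 4 the 51 remaining pairs had a median of -0.01, above 48.1% of random sets. Clustered protocadherin genes held 15 and 14 peaks, against 3.88 and 3.24 at random positions, and imprinted genes 36 and 36, against 19.4 and 17.2. Germline genes held 12 and 18 peaks, against a mean of 5.80 and 5.01 and a maximum of 13 and 11 at random positions, and vomeronasal receptor genes 27 and 11, against 30.6 and 28.0 at random positions. Olfactory receptor genes held 9 and 8 peaks, against 21.9 and 20.5 at random positions, and 0 members had a peak in both genotypes. Histone genes held 0 peaks in both genotypes, against 0.96 and 0.72 at random positions, too few to show a lack of peaks.

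In the immune lists some members had tag-rich H3K9me3 peaks in both genotypes, such as Fcgr3, an Fc receptor gene, with 531 tags in the wild type and 703 in the knockout, Apoe with 48 and 64, and Mapk14 with 57 and 21. Fcgr3, Apoe and Mapk14 also had H3K4me3 at a gene end, with 937 and 1253, 623 and 376, and 619 and 414 tags. H3K9me3 peaks in a single genotype were mostly weaker. Nos2, which encodes inducible nitric oxide synthase, had 23 tags, Ptx3 had 18, Nfkbiz 17 and Ptgs2 15 in the knockout alone, and Csf1 had 17 in the wild type alone. Socs1, an inhibitor of cytokine signalling, had 60 tags and Tbk1, an antiviral kinase gene, had 36 in the knockout alone. Tlr1 had 22 tags in the wild type alone. Dnmt3a and Ehmt2, a DNA and an H3K9 methyltransferase gene, had 56 and 47 tags in the wild type alone. In the lowest score class 17.1% of wild-type and 19.6% of knockout peaks had a partner.

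The third comparison asked where the marks met. H3K9me3 peaks overlapped H3K4me3 peaks of the same genotype in 22.4% of cases in the wild type (21.8 to 23.0%) and in 33.7% in the knockout (33.0 to 34.4%), against 2.01% and 1.80% at random positions. H3K9me3 peaks at H3K4me3 peaks of either genotype numbered 5239 in the wild type and 6383 in the knockout, and those elsewhere 14040 and 10986. Ends of protein-coding genes held 13.2% of the wild-type and 18.6% of the knockout H3K9me3 peaks. The share of H3K4me3 peaks with an H3K9me3 peak was higher in the knockout in all 10 tag deciles. The H3K9me3 pairs at H3K4me3 peaks outside zinc finger genes, 2054 of at least 20 tags, had a median scaled log2 ratio of -0.004 in tag density, 0.07 in tags per peak and 0.08 in unscaled width; peaks called in 1 genotype alone are not among them. In all, H3K9me3 peaks at H3K4me3 peaks held 199101 tags in the wild type and 243722 in the knockout, 1.19 times as many per filtered tag.

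**Figure D4:**
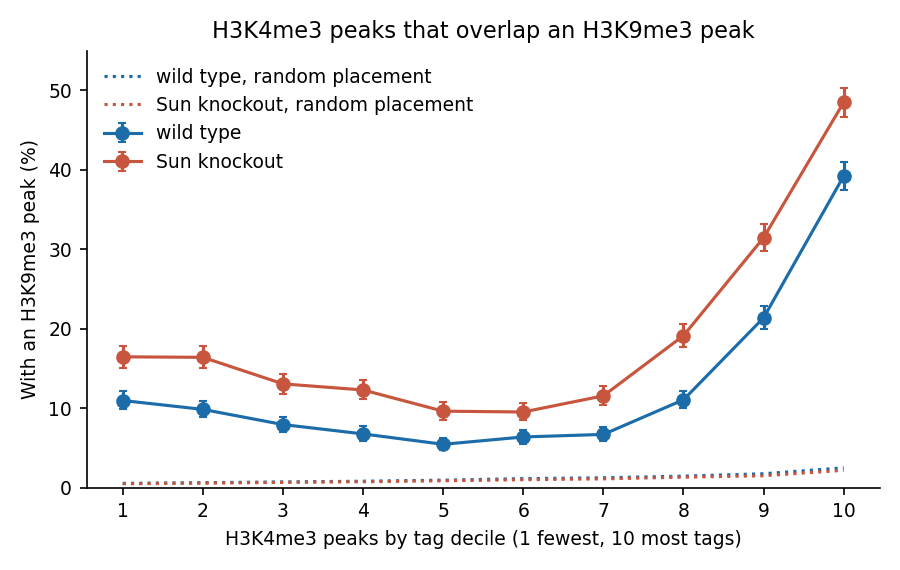
Share of H3K4me3 peaks (%) that overlap an H3K9me3 peak of the same genotype, by decile of H3K4me3 tags, with 95% binomial intervals; 1 library per mark and genotype, dotted lines are random placements. In the top decile the share is 39.2% in the wild type and 48.5% in the knockout, against 2.52% and 2.21% at random positions.

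Peaks on chromosome X made up 2.06% of the H3K4me3 list in the wild type and 2.05% in the knockout, and 2.26% (2.06 to 2.48%) and 2.06% (1.85 to 2.28%) of the H3K9me3 lists. At a score of at least 100 the H3K9me3 shares were 2.44% and 1.84%. The 398 H3K4me3 pairs on chromosome X had a median centred log2 ratio of -0.09, the lowest of all chromosomes.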

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

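The tests of explanations in this part were chosen after the patterns were seen, and the values they measure had been seen too, except for the count of nearby knockout peaks and the count of peaks in other genes of the size of Ctnnb1.

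The marks moved in opposite directions between the genotypes in several summaries of the lists, with 1 library for each value, and the difference between marks was not tested. Knockout minus wild type, the median peak width changed by -44 bp for H3K4me3 and by 13 bp for H3K9me3. The median tags per peak changed by -10 and 1, and the tags per kb of peak by -22.4 and 1.16. Peaks with a score of at least 100 changed by -2869 and 115, and the median score by -19.95 and 1. None of these values was scaled to depth, which also moved in opposite directions. Filtered tags went from 29681491 to 26748289 for H3K4me3 and from 27727997 to 28586946 for H3K9me3. Other summaries were lower in the knockout for both marks, namely the number of peaks, the covered length, the share of tags in peaks and the median fold enrichment.

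A pattern of tag-rich H3K4me3 peaks in a single genotype took in Zc3h12a, Lrp1, Ppp1r9b and Tnfaip2. A candidate explanation is the caller's background, which was taken from the same wide domain. Among peaks of at least 300 tags, those without a partner had a median score at most 0.17 times that of shared peaks in both genotypes. They were also wider, and this explanation needs both. At 500 tags or more the score ratio was 0.148 in the wild type and 0.303 in the knockout, and at 100 to 200 tags 0.234 and 0.201. Sharing rose with score in all peaks, so low scores without a partner go with other explanations too. The ratio therefore cannot decide between them. A loss or gain of H3K4me3 with Sun stays open, since 52.9% of such wild-type peaks had a knockout peak within 5000 bp and tags outside called peaks were not used here. The Tnf peak, with a score of 486, and the Lrp1 peak, with 349, are among the exceptions to the low scores, and Zc3h12a had 2 wild-type peaks, of 1201 and 197 tags, and 0 knockout peaks within 6000 bp of the gene.

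H3K9me3 peaks lay at H3K4me3 peaks more often in the knockout. A difference in depth (knockout over wild type 1.03 by filtered tags, 0.996 by library totals) is argued against whichever library is deeper, because it would move peaks at and away from H3K4me3 the same way, and their numbers changed 1.22-fold (1.17 to 1.26) and 0.782-fold (0.763 to 0.802). Signal of active promoters carried into the H3K9me3 libraries may add to the overlap, as strong H3K4me3 peaks held an H3K9me3 peak at least 3.29 times as often as the median decile in both genotypes, but the knockout excess was 1.24-fold in the top decile and 1.66-fold over the others, so what it adds to the excess stays open. A change of H3K9me3 with Sun cannot be told apart from a difference between immunoprecipitations, as each genotype had 1 library; the peaks at H3K4me3 held 1.19 times as many tags per filtered tag in the knockout, which is part of the pattern itself.

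The wild-type H3K9me3 peaks in Ctnnb1 held 685 tags. DNA of a spliced Ctnnb1 copy in some libraries could place peaks of different marks on the same segments, and the 2 inner H3K4me3 knockout peaks did coincide with them, but so they did in 84.2% of random placements over that stretch, and exon positions were not used here. Chance spread of weak peaks stays open, as the bound set beforehand was not met (Zfp991 held 10 wild-type peaks) and Ctnnb1 was picked for its peaks, although only 2 of 5094 genes of 20 to 50 kb, Ctnnb1 included, held as many as Ctnnb1, and Zfp991 belongs to the zinc finger genes, which held 3.35 times the random number of peaks. That count does not weigh strength, and each of the 9 Ctnnb1 peaks held more tags, 25 to 136, than the list median of 16. In that sense they were not weak peaks, in 1 library. A loss of H3K9me3 with Sun stays open too, since there was 1 library per genotype.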

How the results depend on the processing

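The H3K9me3 overlap without peaks at H3K4me3 and the pair counts scaled to filtered tags were chosen after seeing the data; the other alternatives were fixed before. Of 107 values recomputed, 45 stayed within the counting interval, or within 1.5 times for counts, 60 moved further and 2 turned sign; causes were not tested. No paired analysis was possible because each group had 1 library, which also rules out leaving out replicates. The planned limit on the false discovery rate was not run, as the lists used hold no such column. Values are given for the wild type, then the knockout. With 50% of the peak, the shared percentages were 69.3 and 79.1 for H3K4me3 and 29.0 and 31.0 for H3K9me3. With a score of at least 100 in both lists they were 80.3 and 94.5, and 48.3 and 46.0. With that score in the list asked they were 93.8 and 98.1, and 76.8 and 75.3, and with equal numbers of peaks 77.0 and 78.1, and 34.4 and 34.3, so under these 3 settings the H3K9me3 order turned. Merging gave 73.2 for wild-type H3K4me3. Away from H3K4me3, H3K9me3 gave 20.6 and 26.3. At that score there were 19615 and 16746 H3K4me3 peaks, and 2823 and 2938 H3K9me3 peaks over 1.45 and 1.63 Mb. H3K4me3 pairs at least 2-fold denser and less dense in the knockout numbered 1 and 11 with filtered tags, 4 denser with library totals, 252 and 24 with tags per peak, 4 and 0 with 100 tags, and 1 less dense with 80% overlap. The H3K4me3 median was -0.087 with library totals, -0.33 with tags per peak, -0.23 with 80% overlap, -0.16 with 20 tags and -0.21 with 100 tags. H3K9me3 pairs at least 2-fold denser and less dense numbered 30 and 8 with tags per peak, 1 denser with library totals and with 20 tags, and 0 less dense with 80% overlap and with 100 tags. The H3K9me3 median turned to 0.014 with tags per peak and to 0.034 with library totals, and was -0.037 with 80% overlap and -0.060 with 100 tags. At a score of 100, chromosome X held 2.53 and 2.47% of H3K4me3 peaks and 1.84% of knockout H3K9me3 peaks, and 38.4 and 50.9% of H3K9me3 peaks overlapped H3K4me3. Genes with H3K4me3 in the knockout alone numbered 161 at that score in both lists. With it in the list asked there were 259 in the wild type alone and 59 in the knockout alone. Genes with H3K9me3 in both, the wild type alone and the knockout alone numbered 767, 625 and 872 with that score in both lists, and 767, 157 and 275 with it in the list asked. Low counts limit the H3K9me3 values, with medians of 16 and 17 tags per peak.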

Other observations

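The values in this part were looked up after the data were seen, and no explanation of them was tested. The same regions led all 4 lists by tags, whatever the mark. On chromosome 14 the peak from 19415351 held 4294 tags in H3K4me3 wild type, and its counterparts held 3982 in H3K4me3 knockout, 5269 in H3K9me3 wild type and 4959 in H3K9me3 knockout. On chromosome 17 the peak from 39842898 held 3123, 3275, 4111 and 4328 tags in the same order. In all, 2410 wild-type H3K4me3 peaks were overlapped by a peak in each of the 3 other lists.

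The H3K9me3 pairs on chromosome 4 had the lowest median scaled log2 ratio of all chromosomes, -0.16 over 122 pairs, against -0.02 over all 799. Named genes there were Zfp981, Zfp993, Zfp984 and Zfp978, and Ahdc1, which went the other way at 0.53. Wide H3K4me3 peaks were fewer in the knockout: peaks of at least 4000 bp made up 1.82% (1.68 to 1.98%) of the wild-type list and 1.37% (1.24 to 1.51%) of the knockout list. The H3K4me3 knockout library was also the smaller, and these shares were not adjusted for depth.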
